A study of Mus musculus with 6 samples.

How the data were processed

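Total RNA from the entire small intestine of 3 Cftr control and 3 Cftr null mice was prepared with TRIzol, per the labels, and hybridized to 1-colour Affymetrix mouse arrays, 1 mouse per array. The deposited values are probe set intensities on a linear scale with 1 decimal, all above 0, and the table of probe genes names the array. The software that turned scans into these intensity values is not given in the sources used here, nor are its background and scaling steps. The equal 2%-trimmed means of the 6 arrays show that the values had been scaled before they were deposited. Detection calls were not used here, so a dim probe set is described only by its level.

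The table held 12488 probe sets, of which 66 control probe sets (names starting AFFX) were set aside. Of the other 12422, 10833 had 1 gene symbol in the platform annotation given, 396 had several and 1193 had none; genes were named only from probe sets with 1 symbol, 8251 genes in all. The Entrez identifiers of 10817 of the 10833 were found in the RefSeq gene table, which changed 0 of the symbols. List members under older names were matched too, except that Si and Slc39a1 were not taken for Sis and Slc40a1, because these older names now belong to other genes.

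Values were used as deposited, since the 6 trimmed means lay within 10% of their median, and turned into log2(value + 12). The pseudocount of 12 is the 10th percentile of the positive values of all arrays. A fold change is therefore on the log2(value + pseudocount) scale, which understates changes of dim genes. A probe set was tested if its value was above 109.7, the 40th percentile of all values, in at least 3 of the 6 arrays, whatever their group, which left 7601. Null and control were compared with limma (version 3.58.1, R 4.3.3; lmFit, and eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. The same model with sex and the interaction of genotype and sex tested whether the effect of genotype differs between the sexes. The labels state no pairing or batch, and none was used. The sample titles are codes that the sources used here do not explain: those of control replicate 1 and null replicate 3 begin alike, and that of control replicate 2 begins unlike the other 5. Where the mean of the lower group on the log2(value + pseudocount) scale lay at or below that of 109.7, the fold is given as a bound: the other group's mean on the same scale against that level. This rule was widened, after the values were seen, from groups with all values at or below the level.

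The gene lists, 26 and a list of sex-linked genes, the filter, the tests and the alternatives were chosen before the data were examined. For the lists, each gene was represented by its brightest tested probe set, and lists with at least 5 genes measured were tested with limma's camera, with a preset correlation between genes of 0.01 and, as an alternative, a correlation estimated per list. Fry was run beside it. Members past the threshold were counted over all probe sets and adjusted over the list alone. Some genes belong to more than 1 list, such as Retnlb, Cat, Ephx2 and Pck1. The rule for the named genes was: Cftr; the 10 largest rises and 10 largest falls among probe sets past the threshold with 1 symbol and no overlap between the groups, 1 probe set per gene; for each list up to 4 members past the threshold with the largest change, or, where none passed, 2 of the brightest, as values; and the sex-linked genes. Other genes named, such as Aldh1a1, Ppara, Lct, Slc7a8, Ltf, Reg3a, Kit, Tpsb2, Chil3, Tff3, Zg16, Fcgbp and Fabp4, and those of the observations at the end, were chosen after their values were seen.

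The alternatives were quantile normalization, scaling to equal medians, pseudocounts of 3 and 48, no filter and a filter at 288.7 (the 60th percentile), sex as a covariate, males only, eBayes without a trend and with robust variance, and leaving out each mouse in turn. For lists they were also the mean over a gene's probe sets, leaving out probe sets whose names mark possible cross-hybridization, and the estimated correlation. Names ending in s, f, r, i, g or x before _at were all read as such a mark, here and wherever it is mentioned. These endings were not told apart, and some may not stand for cross-hybridization. Leaving out the member with the largest change of each list was added after seeing the data.

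The functions were tested on simulated data, 20 data sets of 7601 probe sets with the control means and the within-group spreads of the real ones. For null against control, with 200 probe sets changed, 56.4% of 2-fold and 90.0% of 4-fold changes were recovered, 4.5% of calls were false, and data with no change gave 0 calls. A list of 30 independent genes shifted by 0.5 was called in 20 of 20 data sets with either correlation setting, and 0.0% of the other lists were. The interaction of genotype and sex recovered 84.5% of 16-fold differences, with 144 false calls over the 20 data sets. Correlation between genes was left out of these simulations. The control probe sets, tested on their own, gave 0 calls with limma and 1 of 66 at an unadjusted p under 0.05. Log2 values of arrays correlated at 0.947 to 0.972 within groups and 0.909 to 0.951 between groups, across probe sets, which are not independent replicates. The first principal component (45.8% of the variance) separated the genotypes. On the second (21.6%), control replicate 2 (-24.06) and null replicate 3 (-14.95) stood apart from the other 4 arrays, which lay between 2.89 and 14.64.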

Results

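Gene expression was measured in the entire small intestine of 6 mice aged 40 days, 3 of them Cftr control (+/+) and 3 Cftr null (-/-), all congenic on the black6 background. Cftr encodes the cyclic AMP-regulated chloride and bicarbonate channel of epithelial cells, whose loss causes cystic fibrosis. Per the labels, the mice received the liquid diet Peptamen from day 10 of life, so that the gut would not become blocked, and the RNA of 1 mouse was used per array. Each group held 2 males and 1 female, and the females were control replicate 3 and null replicate 2. The arrays were 1-colour Affymetrix arrays, and their values were scaled intensities in arbitrary units. The 2%-trimmed mean was 500.3 on each of the 6 arrays. The number of mice limits the precision of every value. The ratio of the 3' to the 5' probe set of actin lay between 1.12 and 1.20 over the 6 arrays, and that of Gapdh between 0.749 and 0.826.

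The comparison asked which genes differ in the small intestine of mice that lack Cftr. The Cftr transcript itself was read in every mouse first. The brightest of its probe sets gave 801.6, 1017.5 and 1002.0 in control replicates 1 to 3 and 325.9, 295.6 and 368.5 in null replicates 1 to 3. The means were 940.4 ± 120.4 (SD, n = 3) in controls and 330.0 ± 36.6 (SD, n = 3) in nulls, so that Cftr fell by 1.48 on the log2 scale (SE 0.15, adjusted p = 0.00421). The 2 other Cftr probe sets were too dim to be tested. Which part of the gene was altered is not stated in the labels, so it is unknown whether the probes lie inside it. The sex-linked transcripts matched the labelled sexes: Xist was between 1636 and 1932 in the females and between 10.3 and 24.1 in the males. The Y-linked Eif2s3y was between 226.9 and 396.2 in males and at most 30.8 in females, Uty was at least 72.8 in males and at most 18.4 in females, and Kdm5d was at least 41.1 in males and at most 14.4 in females.

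In the small intestine of Cftr null mice, transcripts of the mucosal mast cell proteases Mcpt1 and Mcpt2 and of the goblet cell product Retnlb rose. So did those of 5 of 23 acute phase and epithelial defence genes, Retnlb being counted among the 5. Transcripts of 17 of 57 genes of drug metabolism, 11 of 31 of fatty acid oxidation and 5 of 30 of brush border proteins fell. As lists these were called with a preset correlation between genes, but none was with an estimated correlation (adjusted p = 0.233 each for these 4 lists). Of 7601 probe sets tested, 86 were higher and 142 lower in null mice. The fitted change was at least 2-fold in 56 and 82 of them, though some of these have a bound under 2-fold, such as Cxcl1 (1.89-fold). Of the 86 and 142 probe sets, 200 had 1 gene symbol, and these stood for 66 distinct genes that rose and 121 that fell. The other 28 had no single gene symbol. Groups did not overlap in any of the 228 changed probe sets, and did not overlap in 23.8% of all tested probe sets, where chance gives 10%. At an unadjusted p under 0.05 there were 1313 probe sets, against 380 expected by chance. The counts depended on single mice: 31 rose and 45 fell without control replicate 1, 68 and 87 without control replicate 2, 17 and 35 without null replicate 1, and 28 and 56 without null replicate 3. In each of these fits, as in those without control replicate 3 or null replicate 2, all 228 kept their direction. With groups that do not overlap, leaving out a mouse cannot reverse a direction, so this is no sign of stable calls.

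**Figure D1:**
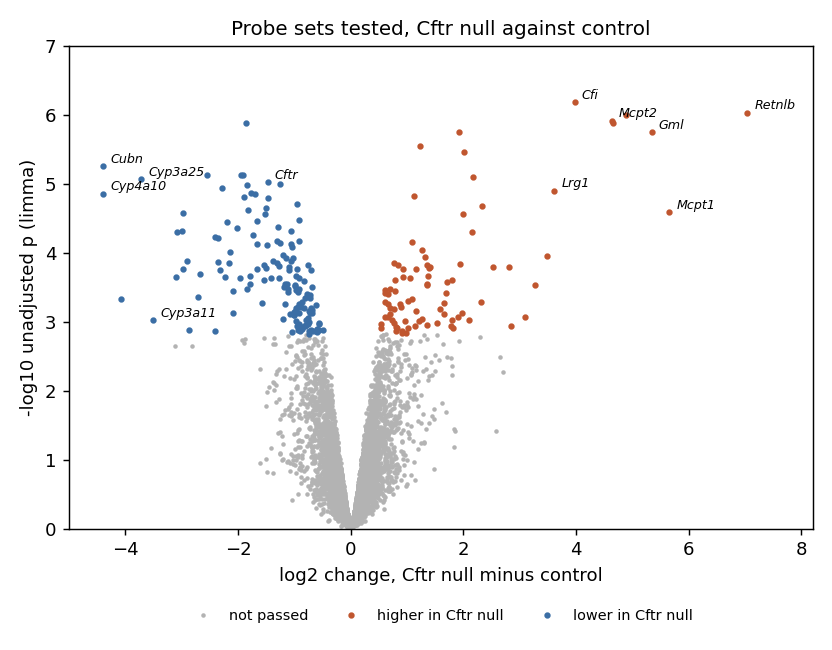
Each point is 1 of the 7601 probe sets tested, with its log2 change (Cftr null minus control, 3 mice each) on the horizontal axis and minus log10 of the unadjusted limma p on the vertical axis. The 86 probe sets higher and the 142 lower in null mice at an adjusted p under 0.05 are coloured, and Retnlb lies farthest to the right.

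Rises and falls were ranked by the fitted log2 change, so a gene given with a low bound can rank high. Retnlb, the goblet cell peptide RELM-beta, was among the largest rises. Its mean was 19.4 ± 2.84 (SD, n = 3) in controls, under the filter level, and 4983 ± 2977 in nulls, at least 34.0-fold higher (adjusted p = 0.00169). The mucosal mast cell proteases Mcpt1 and Mcpt2 were at least 33.4-fold (4394 ± 1959 against 93.3 ± 87.2, adjusted p = 0.006) and 24.4-fold higher (3247 ± 1672 against 109.0 ± 21.6, adjusted p = 0.00169). Gml was at 801.0 ± 404.4 in nulls and 6.60 ± 4.74 in controls, at least 6.08-fold higher. The complement regulator Cfi was at least 7.20-fold higher, at 871.1 ± 128.0 against 46.3 ± 22.5, and Cfhr2, a complement factor H-related gene, at least 5.51-fold higher. The probe sets of Mcpt1 and Cfhr2 have names that mark possible cross-hybridization; a second probe set for Mcpt1, with such a name too, rose from 31.5 to 1366, and a second for Cfhr2, at 5.80 and 10.1, was too dim to be tested. Lrg1, a secreted leucine-rich glycoprotein, rose 12.3-fold, and the acute phase protein Saa3 was at least 2.73-fold higher. Tat, tyrosine aminotransferase, was at least 5.77-fold higher, with null values from 375.9 to 1502. Cpa3, the mast cell carboxypeptidase, was at least 2.0-fold higher.

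Among the largest falls was that of Cubn, the cubilin receptor of the ileal brush border. Its brighter probe set was at 3852 ± 777 (SD, n = 3) in controls and 196.3 ± 143.4 in nulls, 21.1-fold lower (adjusted p = 0.00386), whereas a second, dim probe set for Cubn was at 122.5 and 123.2. The fatty acid hydroxylase Cyp4a10, under the filter level in all nulls, was at least 6.88-fold lower, at 31.8 ± 20.5 against 875.8 ± 345.8. The probe sets of Cyp4a10 and Ugt2b5 and the brighter one of Cubn also have names that mark possible cross-hybridization. The drug-metabolizing enzymes Cyp3a25 and Cyp3a11 fell 13.2-fold and 11.3-fold, the glucuronosyltransferase Ugt2b5 8.63-fold, and the drug efflux pump Abcb1a 8.01-fold. Of enzymes of gluconeogenesis, Fbp1 fell 8.50-fold and Pck1 was at least 7.21-fold lower. Rdh7, a retinol dehydrogenase, fell 7.85-fold and Dio1, a thyroid hormone deiodinase, was at least 6.82-fold lower. The 20 genes of the largest rises and falls were chosen for groups that do not overlap. Leaving out 1 mouse could therefore not reverse their direction. Of the 20, 13 passed the test without null replicate 1, 13 without null replicate 3 and 16 without control replicate 1.

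**Figure D2:**
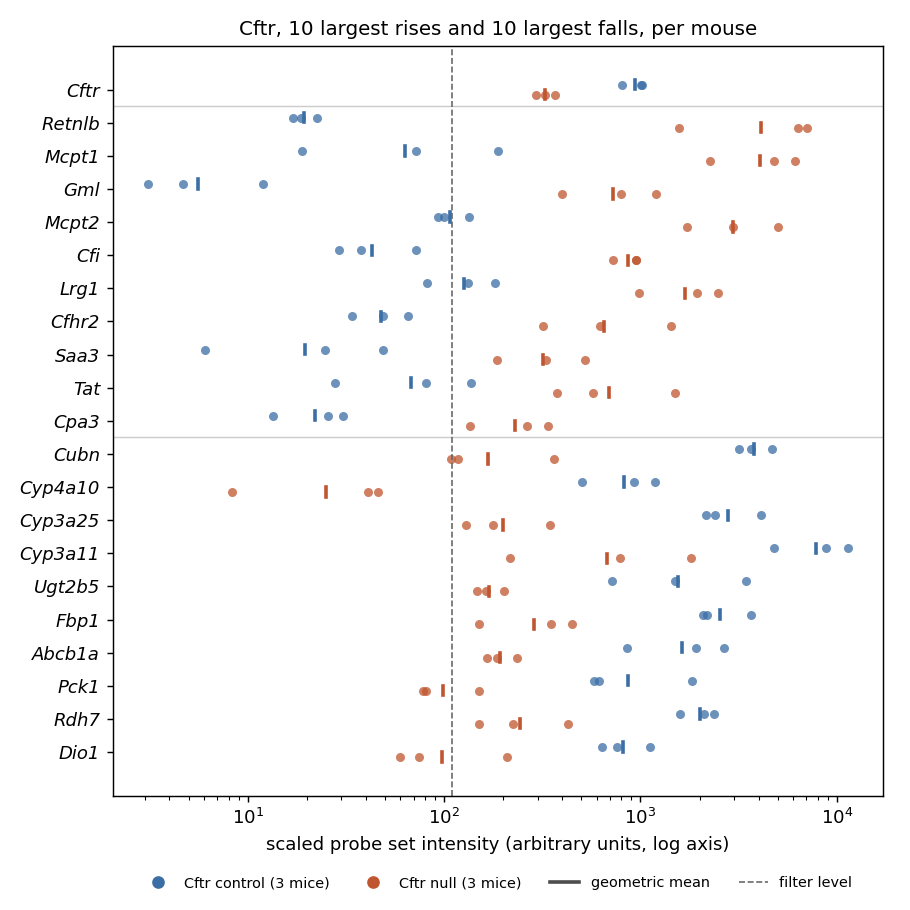
Scaled probe set intensity (arbitrary units, log axis) of Cftr and of the 10 genes with the largest rise and the 10 with the largest fall, 1 point per mouse (3 Cftr control, 3 Cftr null), with short bars at the geometric means and a dashed line at the filter level of 109.7. Apart from Cftr, genes were chosen only where the 3 control values lie apart from the 3 null values. This also held for Cftr, with 801.6 to 1017.5 against 295.6 to 368.5.

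Of 57 genes of xenobiotic metabolism measured, 17 fell and 0 rose, and 34 fell when adjusted over the list alone. The median log2 change was -0.76 (camera adjusted p = 1.53e-19), but the call was lost (adjusted p = 0.233 with an estimated correlation). Besides Cyp3a25, Cyp3a11, Ugt2b5 and Abcb1a, the falls included the aldehyde dehydrogenase Aldh1a1 (log2 change -2.42), the alcohol dehydrogenase Adh1 (log2 change -2.16) and the cytochrome P450s Cyp2b10 (log2 change -2.10) and Cyp2d26 (log2 change -1.90). Without control replicate 1, null replicate 1 or null replicate 3, the members that fell numbered 9, 6 and 8.

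Of 31 genes of fatty acid oxidation and ketogenesis, 11 fell and 0 rose, and 19 fell when adjusted over the list alone. The median log2 change was -0.50 (camera adjusted p = 9.38e-15), but the call was lost at an adjusted p = 0.233 with an estimated correlation. Besides that of Cyp4a10, the largest falls were those of Pdk4, the kinase that restrains pyruvate dehydrogenase (at least 6.39-fold), catalase, Cat (3.55-fold), and the peroxisomal thiolase Acaa1b (3.45-fold). A second Cat probe set did not pass, at a log2 change of 0.26. Ppara, the nuclear receptor that regulates many of these genes, fell as well, from 1321 to 534.6. Without control replicate 1, null replicate 1 or null replicate 3, the members that fell numbered 4, 3 and 7.

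Of 30 genes of brush border digestion and nutrient transport, 5 fell and 0 rose; adjusted over the list alone, 12 fell and 1 rose. Besides Cubn these were the peptidases Mme (4.68-fold lower) and Ace (2.78-fold lower, 1060 ± 268 against 2943 ± 492), the alkaline phosphatase Akp3 (3.84-fold lower) and the amino acid transporter Slc7a8, at 320.8 against 741.4. Lactase, Lct, did not pass, with 11037 in controls and 2033 in nulls (adjusted p = 0.0606). The list's camera adjusted p was 2.92e-07, with a median log2 change of -0.48 (adjusted p = 0.233 with an estimated correlation). Without null replicate 1 or null replicate 3, 2 and 3 members fell. Of 36 lipid absorption and lipoprotein genes, 3 fell and 0 rose, and adjusted over the list alone 15 fell and 2 rose. The 3 were the fatty acid transporters Slc27a2 (4.05-fold lower) and Slc27a4 (1.97-fold lower) and the lipoprotein receptor Scarb1 (1.84-fold lower). Its median was -0.42 (camera adjusted p = 3.82e-05; adjusted p = 0.233 with an estimated correlation), and 0 members passed without null replicate 1, 1 without control replicate 1 and 1 without control replicate 3.

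Of 17 cholesterol synthesis genes, 3 rose and 0 fell; adjusted over the list alone, 10 rose and 1 fell. The median was 0.89 (camera adjusted p = 1.65e-05; adjusted p = 0.233 with an estimated correlation). The 3 were Sqle, squalene epoxidase (3.46-fold, 2176 ± 815 against 607.9 ± 157.9), Idi1, isopentenyl diphosphate isomerase (2.40-fold), and Mvd, mevalonate decarboxylase (at least 3.07-fold). Without null replicate 1, 0 members passed, and 1 passed without control replicate 1 or null replicate 3.

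Of 23 acute phase and epithelial defence genes, 5 rose and 1 fell, and adjusted over the list alone 8 rose and 1 fell. Retnlb, Cfi, Lrg1 and Saa3 led the list. The fifth, the iron-binding protein lactoferrin, Ltf, was at least 1.32-fold higher, and the antimicrobial lectin Reg3a fell, from 6918 to 4511. The list's median was 0.46 (camera adjusted p = 1.65e-05; adjusted p = 0.233 with an estimated correlation). Without null replicate 1 or null replicate 3, 3 members rose. Of 18 cytokine, chemokine and adhesion genes, 2 rose and 0 fell, and adjusted over the list alone 6 rose and 1 fell. Both are neutrophil-attracting chemokines: Cxcl1 was at least 1.89-fold higher (228.3 ± 80.1 against 28.9 ± 9.46) and Cxcl5 at least 1.43-fold higher. The call (camera adjusted p = 0.0273; adjusted p = 0.246 with an estimated correlation) ended without control replicate 2 (adjusted p = 0.0505) and without null replicate 1 (adjusted p = 0.104).

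Of 8 mast cell genes measured, Mcpt1, Mcpt2 and Cpa3 rose and 0 fell, and the same counts were found when adjusted over the list alone. The other members did not pass, among them Kit, the stem cell factor receptor, at 227.8 in nulls and 225.3 in controls, and the tryptase Tpsb2, at 232.1 and 305.8. The list's mean log2 change was 1.59 and its median 0.11 (camera adjusted p = 0.0273; adjusted p = 0.339 with an estimated correlation). The call ended without control replicate 1 (adjusted p = 0.0615), null replicate 1 (adjusted p = 0.0563) or null replicate 3 (adjusted p = 0.0749). The eosinophil and type 2 response list had only 3 genes measured and was not tested: the interleukin 4 receptor Il4ra was at 763.9 ± 208.7 in nulls and 441.7 ± 92.1 in controls, the chemokine Ccl11 at 134.1 ± 29.6 and 181.7 ± 20.4, and Chil3 at 148.5 and 63.4. None of the 3 passed over all probe sets, and 2 rose when adjusted over the list alone.

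Among epithelial secretory cells, 1 of 18 goblet cell and mucus genes rose, Retnlb, and 0 fell; adjusted over the list alone, 2 rose and 1 fell. The abundant goblet cell genes Tff3 (17302 in nulls, 18058 in controls), Zg16 (13715 and 18009) and Fcgbp (12597 and 16117) did not pass. Spink4 (log2 change 1.33), Muc1 (1.07) and Spdef (0.88) were higher in nulls but did not pass either. Of the 18 genes, 11 had a log2 change above 0 and 7 below 0. The list was called (median 0.24, camera adjusted p = 0.0481; adjusted p = 0.392 with an estimated correlation), but not without control replicate 2 (adjusted p = 0.336), null replicate 1 (adjusted p = 0.104) or null replicate 3 (adjusted p = 0.0844). With Retnlb left out, an alternative chosen after seeing the data, the list was not called (adjusted p = 0.183). Of 6 Paneth cell genes, the pentraxin Mptx1 rose 2.31-fold and 0 fell, with the same counts when adjusted over the list alone (median 0.33, camera adjusted p = 0.172; 0.0433 without control replicate 3). The enteroendocrine list was called lower (median -0.39, camera adjusted p = 0.0273; adjusted p = 0.233 with an estimated correlation). Of its 15 genes, however, the single one that passed, Gch1, an enzyme of tetrahydrobiopterin synthesis, rose 1.86-fold; adjusted over the list alone, 2 rose and 6 fell.

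Of 35 ion, acid-base and water transport genes, 1 rose and 2 fell; adjusted over the list alone, 1 rose and 3 fell. Car4, a membrane-bound carbonic anhydrase, rose 3.23-fold (3801 ± 1083 against 1172 ± 351), but a second, dimmer probe set for it did not pass (log2 change 0.66, adjusted p = 0.128). The water channel Aqp1 fell 3.19-fold and uroguanylin, Guca2b, which stimulates fluid secretion, 2.38-fold. The list was not called (median -0.03, camera adjusted p = 0.249). Of 16 eicosanoid genes, 4 fell and 0 rose; adjusted over the list alone, 4 fell and 1 rose. They were Hpgd, which inactivates prostaglandins (3.63-fold lower, 402.8 ± 44.1 against 1495 ± 184), the epoxide hydrolase Ephx2 (3.42-fold lower), Ptgr1 (2.91-fold lower) and the leukotriene C4 synthase Ltc4s, at 352.2 against 571.6 (median -0.07, camera adjusted p = 0.181). Of 42 oxidative and endoplasmic reticulum stress genes, glutathione reductase, Gsr, rose 2.50-fold, asparagine synthetase, Asns, rose 1.98-fold and Cat fell; adjusted over the list alone, 3 rose and 1 fell. That list was not called (camera adjusted p = 0.944, direction up); its mean log2 change was 0.03 and its median -0.00, so that they differ in sign.

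**Figure D3:**
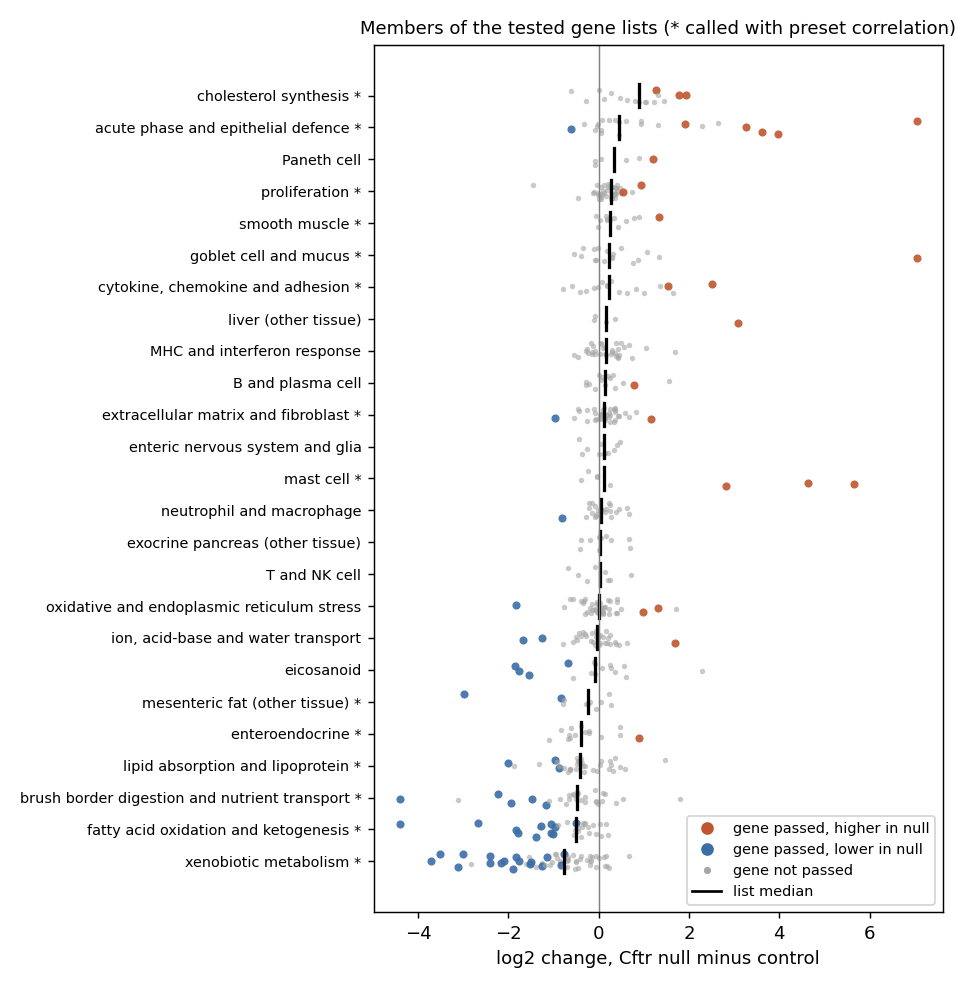
Log2 change (Cftr null minus control) of each measured member of the 25 tested gene lists, 1 point per gene, with a black bar at each list's median and larger coloured points for genes that passed the test. Stars mark the 14 lists called with a preset correlation, 0 of which were called with an estimated correlation; xenobiotic metabolism has the lowest median (-0.76) and cholesterol synthesis the highest (0.89).

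Of 46 proliferation genes, 2 rose and 0 fell, also when adjusted over the list alone: Cks1b (1.92-fold) and Plk1 (1.46-fold), both of the cell cycle. The list's median log2 change was 0.28 (camera adjusted p = 9.84e-05; adjusted p = 0.246 with an estimated correlation). Of 13 smooth muscle genes, gamma-2 actin, Actg2, rose 2.54-fold (7351 ± 1275 against 2904 ± 709) and 0 fell; adjusted over the list alone, 3 rose. The name of the Actg2 probe set, its single one, marks possible cross-hybridization, as do those for Plk1. Its median was 0.26 (camera adjusted p = 0.000981; adjusted p = 0.392 with an estimated correlation). Of 40 extracellular matrix and fibroblast genes, the collagen Col5a2 rose 2.24-fold and the fibulin Fbln1 fell 1.96-fold, with the same counts when adjusted over the list alone. That list was called higher (median 0.13, camera adjusted p = 0.0449; adjusted p = 0.339 with an estimated correlation), but not without control replicate 3 (adjusted p = 0.173), null replicate 1 (adjusted p = 0.104) or null replicate 3 (adjusted p = 0.0905). Of 11 enteric nervous system and glia genes, 0 passed on either count; tubulin Tubb3 was at 2110 ± 505 in nulls and 2082 ± 202 in controls, and galanin, Gal, at 349.9 and 322.8 (median 0.12, camera adjusted p = 0.604).

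Many listed genes of blood-derived cells, mast cells included, were too dim to be tested. Of those on the array, 23 of 41 neutrophil and macrophage, 15 of 22 B and plasma cell and 8 of 25 T and NK cell genes were tested. For mast cells it was 8 of 15. Outside the lists, probe sets for the immunoglobulin variable regions Igkv9-120 and Igkv15-103 rose, as described among the other observations. Of 23 neutrophil and macrophage genes, lysozyme Lyz2 fell 1.76-fold and 0 rose; adjusted over the list alone, 1 rose and 1 fell (median 0.06, camera adjusted p = 0.546). Of 15 B and plasma cell genes, the joining chain of polymeric immunoglobulins, Jchain, rose 1.73-fold and 0 fell, and adjusted over the list alone 2 rose (median 0.15, camera adjusted p = 0.0905; 0.0439 without control replicate 1). Of 8 T and NK cell genes, 0 passed on either count; granzyme A, Gzma, was at 687.6 in nulls and 574.2 in controls, and Cd7 at 535.7 and 723.3. That list's mean log2 change was -0.02 and its median 0.03, so that they differ in sign (camera adjusted p = 0.754, direction down). Of 34 MHC and interferon response genes, 0 passed on either count; H2-K1 was at 13318 in nulls and 14433 in controls, and B2m at 12971 and 14574 (median 0.15, camera adjusted p = 0.253; 0.000155 without null replicate 3).

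Markers of tissues that can lie next to the intestine were measured in the same way. Of 10 exocrine pancreas genes, 0 passed, and 1 rose when adjusted over the list alone; colipase, Clps, was at 2231 ± 628 in nulls and 1952 ± 278 in controls, and Pla2g1b at 1498 and 1228 (median 0.03, camera adjusted p = 0.754). Of 11 mesenteric fat genes, Pck1 and hormone-sensitive lipase, Lipe (1.77-fold), fell and 0 rose; adjusted over the list alone, 3 fell. This list was called lower (median -0.23, camera adjusted p = 0.0244; adjusted p = 0.233 with an estimated correlation), with the fat cell lipid-binding protein Fabp4 at 139.4 in nulls and 117.7 in controls. The call also ended without a filter (camera adjusted p = 0.0589). It ended too without the member with the largest change, an alternative chosen after seeing the data. Of 5 liver genes, Tat rose and 0 fell, with the same counts when adjusted over the list alone (median 0.15, camera adjusted p = 0.187).

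Across the 25 lists tested, 8 were called higher and 6 lower with a preset correlation, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move on balance one way, passed 14 lists at an adjusted p under 0.05, 11 of them also called by camera, and 21 lists for change in either direction. Only fry passed the ion, acid-base and water transport and eicosanoid lists (fry adjusted p = 0.0156 each) and B and plasma cell (0.035). The goblet cell (fry adjusted p = 0.129), smooth muscle (0.112) and extracellular matrix (0.0865) lists were called by camera only. With genes whose control or null mean on the log2 scale lay at or below the filter level counted at their bound, the mean of the mast cell list was 1.28, and the medians of the acute phase and lipid absorption lists were 0.45 and -0.40. Second probe sets for Ace (log2 change -1.12), Aqp1 (-0.75) and Asns (0.86) and 2 for Plk1 (0.48 and 0.55) went the same way as those reported but did not pass.

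A further comparison asked whether the effect of genotype differed between the sexes, with 1 female and 2 males per genotype. Limma's interaction term passed in 0 of 7601 probe sets, with 236 (3.1%) at an unadjusted p under 0.05 and a lowest adjusted p of 0.43. Between females and males, with genotype in the fit, 2 probe sets passed, Eif2s3y and one with no gene symbol, both lower in females. The filter asked for a value above 109.7 in at least 3 arrays, more than there were females. A transcript present only in females, such as Xist, was therefore not tested. In simulated data of the same size, the interaction term recovered 84.5% of 16-fold differences.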

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

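The alternative that leaves out the member with the largest change was chosen after seeing the data; the others were planned. Counts of changed probe sets (86 higher, 142 lower, 228 in all) stayed within 1.5 times under both other scalings, other pseudocounts and filters, sex as a covariate and robust variance; they were 50, 85 and 135 with males only and 49, 92 and 141 without a variance trend. Leaving out 1 mouse gave 17 to 68 higher, 35 to 117 lower and 52 to 182 in all. The count of interactions between genotype and sex was 0 with quantile normalization and without a filter, the alternatives run for it. The 228 kept their direction in every alternative that tested them. Their groups do not overlap, so only the other scalings could have reversed a direction.

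The cause of these and the following differences was not tested. With an estimated correlation, adjusted p was 0.233 for xenobiotic metabolism, fatty acid oxidation, brush border, lipid absorption, cholesterol synthesis, acute phase, enteroendocrine and mesenteric fat; 0.246 for cytokines and proliferation; 0.339 for mast cell and extracellular matrix; and 0.392 for goblet cell and smooth muscle. Ranges over the left-out mice were 0.0127 to 0.336 for goblet cell, 0.0102 to 0.104 for cytokines, 0.00416 to 0.0749 for mast cell, 0.0159 to 0.173 for extracellular matrix, 0.0433 to 0.774 for Paneth cell, 0.0439 to 0.278 for B and plasma cell, 0.000155 to 0.7 for MHC and interferon, 0.265 to 0.906 for T and NK cell, 0.682 to 0.917 for stress and 0.253 to 0.854 for pancreas, the last 4 with a change of direction. Without the member with the largest change, adjusted p was 0.183 for goblet cell, 0.0921 for cytokines, extracellular matrix and mesenteric fat, 0.158 for mast cell and 0.0751 for enteroendocrine, and pancreas turned down (0.841). Without a filter it was 0.0589 for mast cell and mesenteric fat, and liver turned down (0.576). With the stricter filter it was 0.225 for goblet cell and 0.323 for cytokines, 0.0321 for B and plasma cell (higher) and eicosanoid (lower), and T and NK cell turned up (0.604). Without probe sets that may cross-hybridize it was 0.054 for goblet cell, 0.05 for cytokines (not under the threshold), 0.139 for mast cell, and 0.0523 for extracellular matrix and mesenteric fat, while stress (0.881) and pancreas (0.655) turned down. It was 0.0524 for goblet cell with the larger pseudocount, 0.0534 for goblet cell and 0.0505 for extracellular matrix without a variance trend, and 0.0725 for extracellular matrix with males only, where MHC and interferon turned down (0.957).

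Of the values of single named genes under all alternatives, 870 kept direction and side of the threshold, 169 kept direction but did not pass and 10 changed direction; those genes had not passed: Tubb3 (0.019 with quantile normalization, -0.19 to 0.13 over left-out mice), Clps (-0.053 to 0.30), Eif2s3y (-1.39 to 0.84) and Uty (-0.17 to 1.39). Signal over background limits the folds of genes with a group's log2 mean at or under the filter level, which are given as bounds.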

Other observations

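Of the tests in this part, all but that on epithelial genes were chosen after the result was seen. Of the changed genes, 41 that rose and 72 that fell belong to none of the lists, and those named here were chosen after their values were seen. Dmbt1, a mucosal scavenger receptor, rose 2.35-fold (18262 against 7743, adjusted p = 0.00238). Slfn2, a regulator of immune cell growth, rose 4.52-fold and 4.0-fold on 2 probe sets. The names of both have endings read here as a mark of possible cross-hybridization. Capg, an actin-capping protein of phagocytes, rose 4.02-fold and Prom1 2.40-fold, while Il18bp, which neutralizes interleukin 18, was at least 4.03-fold higher and Plet1 at least 4.89-fold higher. Oxct1, the enzyme that lets cells use ketone bodies, rose 3.80-fold. The chymase gene Cma2 rose 4.46-fold on a probe set whose name has such a mark. Among 24 probe sets for immunoglobulin variable regions, those for Igkv9-120 (9314 against 1939) and Igkv15-103 (598.2 against 160.2) rose, and their names carry it too; a second for Igkv15-103 did not pass (log2 change 1.15). Falls included the folate transporter Slc46a1 (3.77-fold), the retinol saturase Retsat (5.89-fold), the arginase Arg2 (6639 to 2353), the kinase Sgk1 (6.51-fold), the brush border scaffold Pdzk1 (4.98-fold), the sterol carrier Scp2 (2.45-fold) and the oxysterol-binding Osbpl1a (at least 3.63-fold).

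The xenobiotic metabolism list had a median log2 change of -0.76. Epithelial genes expressed from crypt to villus had a median log2 change of 0.073 (26 genes, 95% bootstrap interval -0.092 to 0.20), above that of the list, which argues against less epithelium in the RNA of null mice. The actin 3' to 5' ratio of nulls was 1.01 times that of controls (Gapdh 0.977), which argues against more degraded RNA. Abundant brush border and lipid absorption genes were lower too, with a median of -0.47 (25 genes, -0.64 to -0.39). This was above the list's median by 0.29 (0.055 to 0.64). A lower share of absorptive cell RNA may therefore account for part of the fall. The intervals resample genes, which are correlated, and not mice, so whether it accounts for all of the fall stays open. That the loss of Cftr lowers the transcripts of the list within absorptive cells is a hypothesis. These data do not separate it from a lower share of absorptive cell RNA or from effects of intestinal disease. Measuring the transcripts in isolated villus cells of mice before disease would test it.

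The rise of Retnlb and Car4 was weighed against large intestine in the null samples, using Car1, which is abundant in the mucosa of the large intestine. Car1 was at 11.5, 30.6 and 102.8 in null replicates 1 to 3, under the filter level of 109.7, but above the highest control (25.3) in replicates 2 and 3; a requirement that no null exceed the controls was added after these values were seen, and without it the test would have argued against large intestine. In null replicate 1, with Car1 below every control, Retnlb was at 6329 and Car4 at 4168, and 0 of 7 Hox genes of the hindgut were higher in all nulls than in all controls, but Car1 and 6 of these were dim and Hoxb13 (89.3 to 115.4 in controls, 91.1 to 152.6 in nulls) lay near the filter level, so large intestine stays open. The other 17 goblet cell genes had a median log2 change of 0.19 (-0.086 to 0.50), which argues against more goblet cells as the whole cause of the Retnlb rise, if these were to rise at least 2-fold. Induction of Retnlb within goblet cells is a hypothesis, which staining for its product in sections of small intestine would test.

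Control replicate 2 was far from both other controls in 20 probe sets chosen for that distance, lower in 16 and higher in 4. Among the lower were 3 genes of the distal intestine, Fabp6 (100.3, against 7441 and 6099), Fgf15 (6, against 152.9 and 153.8) and Slc34a2 (313.2, against 2693 and 2011), but also Reg3g (2680, against 13439 and 15508), Tff2 (1081, against 6618 and 5766) and Scx (43.7, against 393.2 and 900.9), and among the higher were Gsta2 (1805, against 384.1 and 204.3) and Hnf4g (2496, against 550.4 and 613.2). Less distal intestine in that sample could lower the first 3, and 4 other distal genes had a median log2 difference of -0.53 from the other controls (-0.92 to -0.22; Cubn -0.38, Slc51a -0.68, Gcg -0.22, Mep1a -0.92), against -0.11 for 10 proximal genes; these 4 are too few to decide, but the minimum of 5 was set after their median was seen, and without it the test would have argued against this explanation. Cftr in that sample was 1017.5, far above the nulls (295.6 to 368.5), which argues against a null sample under a control label. In the nulls, Fabp6 (880.2 to 2158.5), Fgf15 (43.8 to 148.5) and Slc34a2 (663.4 to 1983.3) lay between control replicate 2 and the other controls. Whether the nulls held less distal intestine was not tested. The other genes that stood apart in control replicate 2 were not explained, and no biological explanation was tested.

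The 6 mice can be split into 3 against 3 in 10 ways, too few for a share under 0.05. For changed probe sets, 1 of the 10 splits, the real one, gave as many as 228, and the highest other gave 0. For gene lists called with a preset correlation, 1 of the 10 gave as many as 14, and the highest other gave 9. Every other split mixes the genotypes in both of its groups. A genotype effect then widens the spread within groups, which makes calls of probe sets unlikely, and part of it stays between the groups. Neither the 0 nor the 9 is therefore a rate for data without a genotype effect.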
